A study of Mus musculus with 4 samples.

How the data were processed

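Poly(A) RNA from sorted osteoclast progenitors was made into libraries with the Illumina TruSeq Stranded mRNA kit, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.10, HTSeq 0.6.0 and edgeR 3.8.6 and the mouse genome build mm10, without saying what each did or whether counting used strand. The deposited values are a normalized signal per gene, named by the authors as edgeR CPM on the effective library size, that is, the library size multiplied by a normalization factor, so that libraries do not sum to one fixed total. The 4 columns were matched to samples by name, and the WT column whose number differed from the sample title was matched by the sample's description to WT replicate 2.

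Every value of a library was a whole multiple of its smallest value, so whole reads were recovered: 100% of the 18276 values of each library were whole within 0.01 read. The sums came to between 67592972 and 77773478 reads per library. At this depth 3 reads, the limit that a count of 0 allows, correspond to 0.0380 to 0.0428 CPM, which covers counting error only. Each gene had at least 10 reads in its highest library. A total of 18249 genes had a symbol. Positions are from GENCODE M21 on GRCm38, the assembly of mm10, in which 92.19% of the identifiers carried the same version.

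The design, the 27 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The named genes were Paxip1 and a panel of 10 osteoclast genes, the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap and whose higher group averaged at least 5 CPM, and up to 4 members of each list with the smallest p. Further list members, Trim30c and Rpl26 were named after their values were seen. Genes with at least 1 CPM in at least 2 libraries were tested (12357) with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a trended variance prior, 2-sided, with genotype as the only term, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2(CPM + 1) scale, which understates changes of low genes. Means are of CPM, ± SD over 2 libraries. Gene lists with at least 5 tested members (26 of 27) were tested with camera on the same values with a preset correlation of 0.01, and again with an estimated correlation and with fry, and within each list gene p-values were also adjusted over the list alone. All 10 list calls were lost with an estimated correlation, where the smallest adjusted p was 0.689.

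The recovered reads were tested with the edgeR 4.0.16 quasi-likelihood test, which called 660 genes, and with DESeq2 1.42.0, which called 1906. Other settings were pseudocounts of 0.25 and 5, no filter and a filter at 5 CPM, scaling to a common sum or by median-of-ratios factors, a robust variance prior, the replicate number as a block, and each library left out. Added after the data were seen were edgeR with the authors' effective library sizes, limma-voom, the lists without called genes that have a near-identical copy, and the PTIP list without Paxip1. Near-identical copies were transcripts matched by BLAST 2.17.0 at 95% identity or more over at least 50% of the shorter transcript and at least 200 nucleotides.

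On data simulated from the means of these libraries with 200 of 12357 genes changed, limma recovered 28.4% of genes changed by 1.5-fold, 82.1% by 2-fold and 95.5% by 4-fold, with 9 false calls. In the same simulation, camera with the preset correlation called a shifted set of 25 genes and 0 of 20 unshifted sets, and with an estimated correlation the shifted set had an adjusted p of 0.0578. The simulated genes were drawn independently, so false list calls among correlated genes were not tested. Their spread followed the edgeR trend of dispersion with mean expression, so genes that vary more than this trend were not simulated. The replicates were not the same library: the chi-square per degree of freedom of their counts was 54.5 for Ptip_KO and 117 for WT, where sampling noise alone gives about 1.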

Results

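Poly(A) RNA was sequenced from osteoclast progenitors, sorted from fresh mouse bone marrow as cells without B220, CD3 and Mac-1 that carry CD115, the receptor encoded by Csf1r. The mice were on a mixed B6;129 background. In 2 libraries, the cells came from mice with floxed alleles of Ptip (gene symbol Paxip1) and the interferon-inducible Mx-1Cre driver (Ptip_KO), and in 2 libraries from Mx-1Cre mice with wild-type Ptip (WT). PTIP is a subunit of histone H3 lysine methyltransferase complexes. The table held 76184092 and 67592972 reads for Ptip_KO replicates 1 and 2, and 77773478 and 77417411 for WT replicates 1 and 2, so that 1 read was worth between 0.0127 and 0.0143 CPM. The 2 replicates of a group are called independent in the series' description, and no label says that they are separate animals, so the p-values measure the spread between these samples. Across genes, the log values correlated with r = 0.993 between the Ptip_KO libraries and 0.990 between the WT libraries, and with 0.969 to 0.975 between libraries of different groups. WT replicate 2 had 298 CPM of Xist, the transcript of the inactive X chromosome, and 0.101 CPM of the Y-linked gene Ddx3y, while the other 3 libraries had 0.0428 to 0.0814 CPM of Xist and 69.1 to 89.6 CPM of Ddx3y.

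The comparison of Ptip_KO with WT asks which transcripts of osteoclast progenitors differ when Ptip is deleted. Paxip1 fell from 104 ± 1.83 CPM in WT to 4.41 ± 0.970 CPM in Ptip_KO (SD, n = 2 each), with 5.10 and 3.73 CPM in the Ptip_KO libraries and 106 and 103 CPM in the WT libraries. Its log2 fold change was −4.29 with a standard error of 0.144 and a limma adjusted p of 0.000383 (Benjamini-Hochberg). By limma, at least 5 members fell in each of the lists of red cell, class II antigen presentation, macrophage and dendritic cell genes, and the extracellular matrix gene Fn1 and the integrin Itga1 were among the largest decreases. Osteoclast genes as a group did not pass the test, although Acp5, Car2 and Cd9 fell and Trem2 rose. The log2 fold changes of Car2 (−1.63) and Cd9 (−1.59) were close to the median of the red cell list (−1.59). Paxip1 (ENSMUSG00000002221.11) lies on chromosome 5 at 27740080 to 27791691 (mm10), and no other annotated gene overlaps it.

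Of 12357 tested genes, 777 differed at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment, 300 higher and 477 lower in Ptip_KO. At least a 2-fold change was seen for 103 of the higher and 298 of the lower genes. In 6805 genes (55.1%) both Ptip_KO libraries lay on one side of both WT libraries, where chance gives 33.3%. The same direction was called by edgeR for 610 and by DESeq2 for 776 of the 777 genes. Exact permutation of 2 against 2 samples cannot give a two-sided p under 0.333, so the calls rest on the spread that limma shares across genes. The count moved to 452 without Ptip_KO replicate 1, 476 without Ptip_KO replicate 2, 1495 without WT replicate 1 and 1620 without WT replicate 2, and DESeq2 called 1906 genes.

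**Figure D1:**
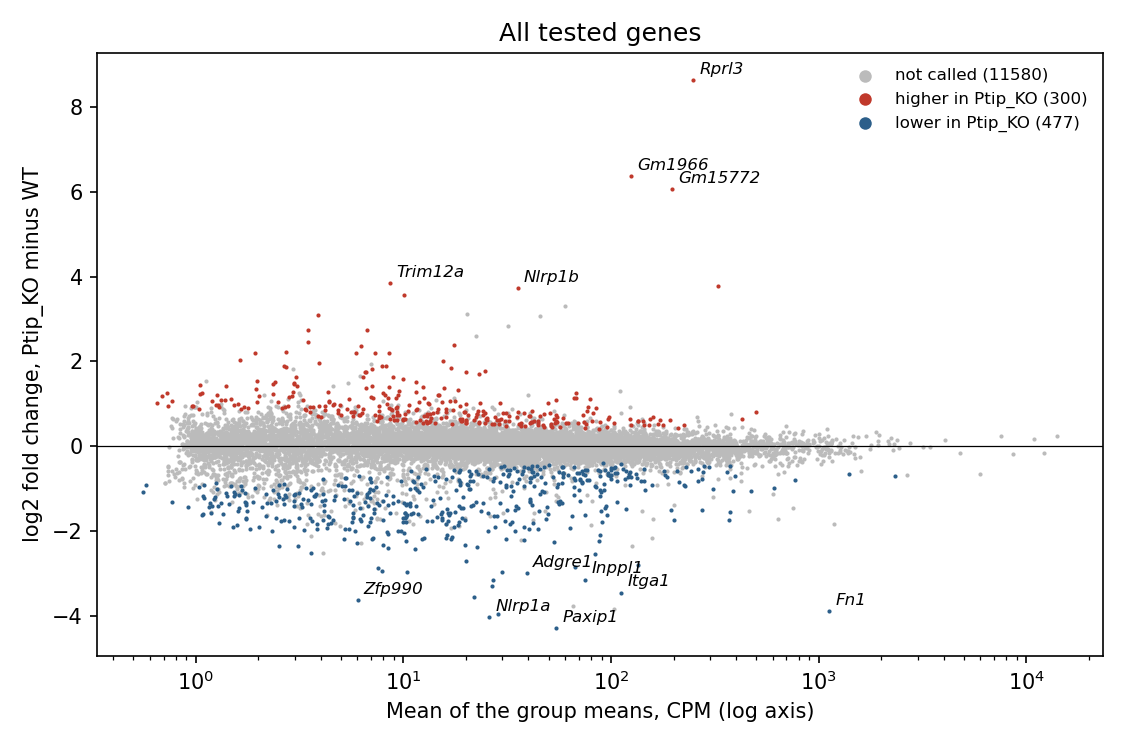
Each point is one of the 12357 tested genes, with the mean of the group means in CPM on a log axis and the log2 fold change of Ptip_KO minus WT. Red points are the 300 genes higher and blue points the 477 genes lower in Ptip_KO, and Fn1 and Paxip1 lie near −3.89 and −4.29.

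Among the genes of osteoclast biology fixed in advance, Acp5, the tartrate-resistant acid phosphatase of osteoclasts, fell from 9.50 ± 0.853 to 4.25 ± 0.549 CPM (SD, n = 2), with a log2 fold change of −1.002 and a limma adjusted p of 0.0229. Its adjusted p was 0.0721 without Ptip_KO replicate 1. Pparg, a nuclear receptor that promotes osteoclast differentiation, was at 0.880 and 0.4995 CPM in Ptip_KO and 2.55 and 1.88 CPM in WT, and missed the threshold at a limma adjusted p of 0.0626, with 0.0158 without WT replicate 2 and 0.0107 by DESeq2. Csf1r, the receptor used in the sort, was at 804 ± 30.2 CPM in Ptip_KO and 641 ± 50.3 CPM in WT (SD, n = 2; limma adjusted p = 0.149), and DESeq2 gave 0.00317. The RANK gene Tnfrsf11a, the transcription factors Nfatc1, Spi1 and Fos, and the integrin Itgb3 did not pass, with limma adjusted p between 0.393 and 0.983. Ctsk, the osteoclast protease cathepsin K, had between 0.0788 and 0.393 CPM and was under the filter, and Dcstamp was not analysed here. Acp5 lies on chromosome 9 at 22126727 to 22135711 and overlaps a gene on the opposite strand, and Pparg lies on chromosome 6 at 115360951 to 115490399.

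**Figure D2:**
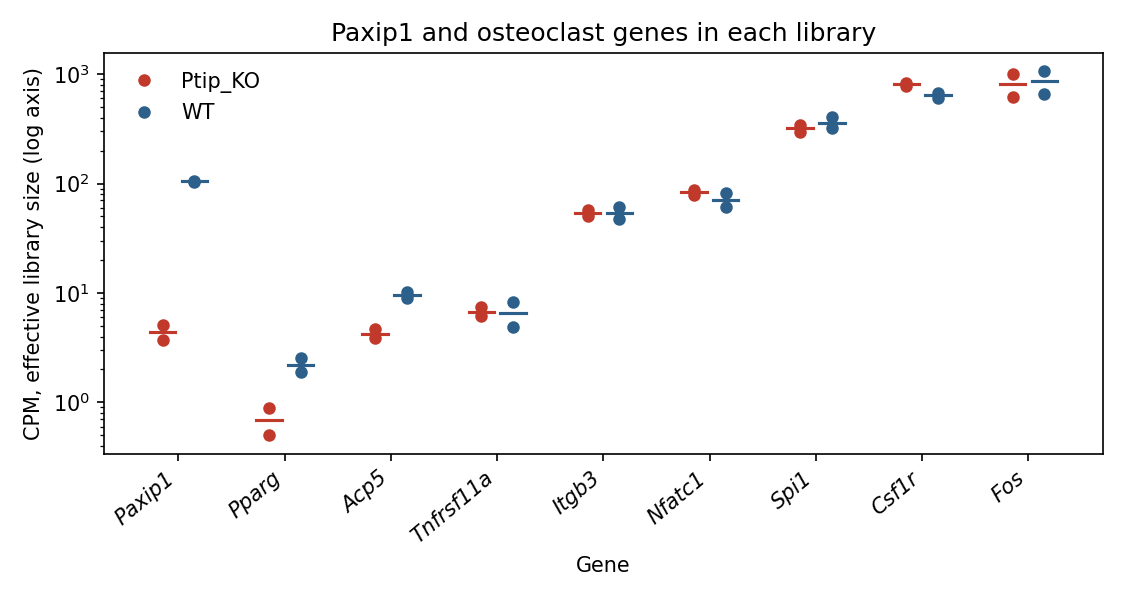
Points are the 4 libraries, red for Ptip_KO and blue for WT, in CPM on a log axis, and bars are group means. Paxip1 is at 3.73 and 5.10 CPM in Ptip_KO and near 104 CPM in WT, while the points of Tnfrsf11a, Itgb3, Nfatc1, Spi1 and Fos from both groups overlap.

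In the osteoclast differentiation list, 1 of 29 tested members rose and 3 fell, and adjusted over the list alone the counts were also 1 and 3. Without WT replicate 1 and by DESeq2, 2 rose and 5 fell, and 1 fell when rescaled to a common sum. Trem2, a receptor of myeloid cells, rose from 39.5 ± 1.24 to 95.5 ± 11.98 CPM (SD, n = 2). The carbonic anhydrase Car2, which acidifies the resorption space, fell from 145 ± 35.3 to 46.2 ± 12.5 CPM, and the tetraspanin Cd9 from 25.1 ± 5.05 to 7.67 ± 1.28 CPM. The log2 fold changes of Car2 (−1.63) and Cd9 (−1.59) lay inside the interquartile range of the red cell genes described below (−1.74 to −1.40). Whether Car2 and Cd9 fell along with the red cell genes or as part of an osteoclast programme was not tested. The osteoclast differentiation list as a whole had a camera adjusted p of 0.386. In the PPAR gamma list, 4 of 25 tested members fell, among them the transcription factor Cebpb, from 196 ± 3.25 to 95.8 ± 10.6 CPM, and the acyl-CoA synthetase Acsl1, from 151 ± 3.38 to 89.9 ± 1.03 CPM. Adjusted over the list alone, 4 members rose and 8 fell, and the camera adjusted p was 0.0579. This list passed with no filter (camera adjusted p = 0.00671), without Ptip_KO replicate 2 (0.0319), without WT replicate 2 (0.0262) and on recovered reads by edgeR (0.0374), and 2 members rose and 7 fell without WT replicate 1, 2 and 8 without WT replicate 2, and 4 and 7 by DESeq2. In the PTIP and COMPASS list, 1 of 17 members, Paxip1, fell, 16 had a negative log2 fold change, the median was −0.14, and adjusted over the list alone Paxip1 alone fell. Its camera adjusted p was 0.0342, with an adjusted p = 0.774 with an estimated correlation and a camera adjusted p of 0.161 without WT replicate 1. Without Paxip1 itself, the median was −0.13 and 15 of 16 members had a negative log2 fold change. The list then lost the call (camera adjusted p = 0.103, with a mean of −0.113 against −0.359 with Paxip1), so the call of the full list rests on the deleted gene. Without WT replicate 1 or 2, 2 members fell, with medians of −0.05 and −0.22.

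Several of the genes with the largest changes belong to families of close relatives that sit side by side. Nlrp1b rose from 4.14 ± 0.652 to 66.8 ± 0.443 CPM (SD, n = 2), and its neighbour Nlrp1a fell from 49.6 ± 9.52 to 2.06 ± 0.0337 CPM. Both encode inflammasome sensors and lie on chromosome 11, Nlrp1b (ENSMUSG00000070390.12) at 71153102 to 71230733 and Nlrp1a (ENSMUSG00000069830.10) at 71092236 to 71144704. On chromosome 7, the tripartite motif genes Trim12a (104299894 to 104315466), Trim5 (104263386 to 104288094) and Trim30d (104470014 to 104507849) rose by 3.85, 2.75 and 2.75 on the log2 scale, while Trim30c fell by 1.04. Gm1966, an unprocessed pseudogene further along chromosome 7 (106596743 to 106604035), rose from 2.01 ± 0.309 to 247 ± 0.641 CPM. Of 26 tested genes from Trim34a to Gm1966, 6 were called higher and 1 lower. Trim34a (1.40 on the log2 scale) was among the higher ones, while Trim12c, Trim30a, Trim30b, Trim34b and Trim3 were not called. Trim34a and Trim34b match at 98.7% of aligned positions, so the counts of either gene are uncertain.

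The other large increases were mostly pseudogenes or RNA genes. Gm15772, a processed pseudogene on chromosome 5 at 3236431 to 3236868, rose from 4.87 ± 0.381 to 388 ± 3.79 CPM (SD, n = 2), and Rpl26, the ribosomal protein gene on chromosome 11 at 68901583 to 68906989 that it matches at 98.2% of positions, fell from 559 ± 2.75 to 191 ± 2.21 CPM. Rpl26 is not a member of the ribosomal protein list tested below, and counts of either gene are uncertain because of this match. The same caution holds for Gm15459, Gm3375, Gm47283 and Trim5 among the increases and for Eno1b, Zfp990 and Rps13-ps1 among the decreases, each of which has at least 1 near-identical copy. It holds as well for Cycs, named below, which has 4 such copies. Gm47283 lies on chromosome Y, and had 20.3 and 18.6 CPM in the Ptip_KO libraries. In WT replicate 1, which has reads of the Y-linked gene Ddx3y, it had 1.13 CPM, and in WT replicate 2 it had 0.418 CPM. Rprl3, an RNA gene on chromosome 8, rose from 0.210 ± 0.0286 to 498 ± 204 CPM.

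Fn1, Itga1, Adam19, Vcan and Inppl1 were among the 10 largest decreases. Fn1, which encodes fibronectin, fell from 2105 ± 1287 to 137 ± 72.2 CPM (SD, n = 2; limma adjusted p = 0.0187), with 3015 and 1195 CPM in the WT libraries, and had a limma adjusted p of 0.0724 with a robust variance prior. Fn1 lies on chromosome 1 at 71585520 to 71653200. The collagen-binding integrin Itga1 fell from 207 ± 58.9 to 17.9 ± 5.22 CPM, the metalloprotease Adam19 from 49.4 ± 11.3 to 4.69 ± 1.55 CPM, and the phosphoinositide phosphatase Inppl1 from 135 ± 7.49 to 14.4 ± 1.42 CPM. Vcan, which encodes the proteoglycan versican, fell from 49.6 ± 38.6 to 3.64 ± 2.23 CPM by limma, and missed the threshold by edgeR at an adjusted p of 0.0564. Itga1 overlaps Pelo on the same strand and Inppl1 overlaps Phox2a on the opposite strand, so these counts can include reads of the neighbour.

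Red cell genes had the lowest median of the 26 tested lists. Of 23 tested erythroid members, 15 fell and none rose, all 23 had a negative log2 fold change, and the median was −1.59. Adjusted over the list alone, 21 fell. The count that fell was 6 when rescaled to a common sum, 7 by edgeR, 7 by limma-voom, 8 with a robust variance prior and 9 with median-of-ratios factors, and 20 by DESeq2, 12 without Ptip_KO replicate 1, 20 without Ptip_KO replicate 2, 22 without WT replicate 1 and 20 without WT replicate 2. The alpha globin gene Hba-a1 averaged 163 CPM in Ptip_KO and 580 CPM in WT (log2 fold change −1.74), and Hba-a2 averaged 90.3 and 314 CPM. Hba-a1 and Hba-a2 match at 99.8% of aligned positions, so their reads may not be told apart. The haem synthesis enzyme Alas2 averaged 38.4 and 143 CPM, and Hemgn fell from 51.5 ± 10.005 to 14.0 ± 4.08 CPM (SD, n = 2). The transferrin receptor Tfrc fell by 0.65 on the log2 scale, with a limma adjusted p of 0.0795 without Ptip_KO replicate 1 and 0.0508 without Ptip_KO replicate 2. Beta globin Hbb-bs averaged 471 CPM in Ptip_KO and 1910 CPM in WT, at a limma adjusted p of 0.0927. The camera adjusted p of the list was 4.26e-14, and adjusted p = 0.746 with an estimated correlation.

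Class II antigen presentation, dendritic, macrophage and neutrophil lists were lower in Ptip_KO as well. In the class II list, 1 of 12 tested members rose and 5 fell (adjusted over the list alone, 1 and 8), with a median of −0.85, a camera adjusted p of 0.00627 and an adjusted p = 0.746 with an estimated correlation. By limma-voom, 1 rose and 1 fell, and without WT replicate 1 or 2, 2 rose and 6 and 7 fell. H2-Aa fell from 29.4 ± 11.95 to 7.06 ± 0.153 CPM (SD, n = 2) and H2-Eb1 from 17.2 ± 6.14 to 4.97 ± 0.262 CPM, while H2-Oa, which modulates peptide loading, rose from 6.43 ± 0.963 to 18.5 ± 1.34 CPM. Of 15 dendritic cell members, 1 rose and 5 fell (adjusted over the list alone, 1 and 6), with a median of −0.27, a camera adjusted p of 0.000147 and an adjusted p = 0.689 with an estimated correlation. The median was −0.58 without WT replicate 1 and −0.47 without Ptip_KO replicate 1. Id2 fell from 29.3 ± 6.19 to 7.74 ± 0.251 CPM and Itgax from 17.1 ± 0.817 to 5.82 ± 1.09 CPM, while Tcf4, a transcription factor of plasmacytoid dendritic cells, rose from 59.9 ± 6.32 to 104 ± 0.585 CPM. Of 26 monocyte and macrophage members, 5 fell and none rose (adjusted over the list alone, 8 fell), with a median of −0.45, a camera adjusted p of 0.000418 and an adjusted p = 0.746 with an estimated correlation. Without WT replicate 1, 2 rose and 9 fell with a median of −0.29, without WT replicate 2, 13 fell, and by DESeq2, 1 rose and 10 fell. Adgre1, which encodes F4/80, fell from 71.1 ± 27.4 to 7.73 ± 1.33 CPM, and the scavenger receptors Mrc1 and Cd163 fell by 1.38 and by 1.53 on the log2 scale. Of 24 neutrophil and granule members, 2 fell and none rose (adjusted over the list alone, 8 fell), with a median of −0.80, a camera adjusted p of 6.46e-05 and an adjusted p = 0.746 with an estimated correlation. Without WT replicate 1, 16 fell with a median of −1.20, without WT replicate 2, 8 fell with a median of −0.39, and without Ptip_KO replicate 1, 10 fell and 1 rose. DESeq2 called 9 lower, the fit with no filter 5, edgeR with no filter 4, and limma-voom and rescaling to a common sum 1 each. Padi4 fell from 52.3 ± 8.14 to 14.4 ± 2.09 CPM, and S100a9 was at 299 ± 118 CPM in Ptip_KO and 978 ± 373 CPM in WT (limma adjusted p = 0.0509).

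**Figure D3:**
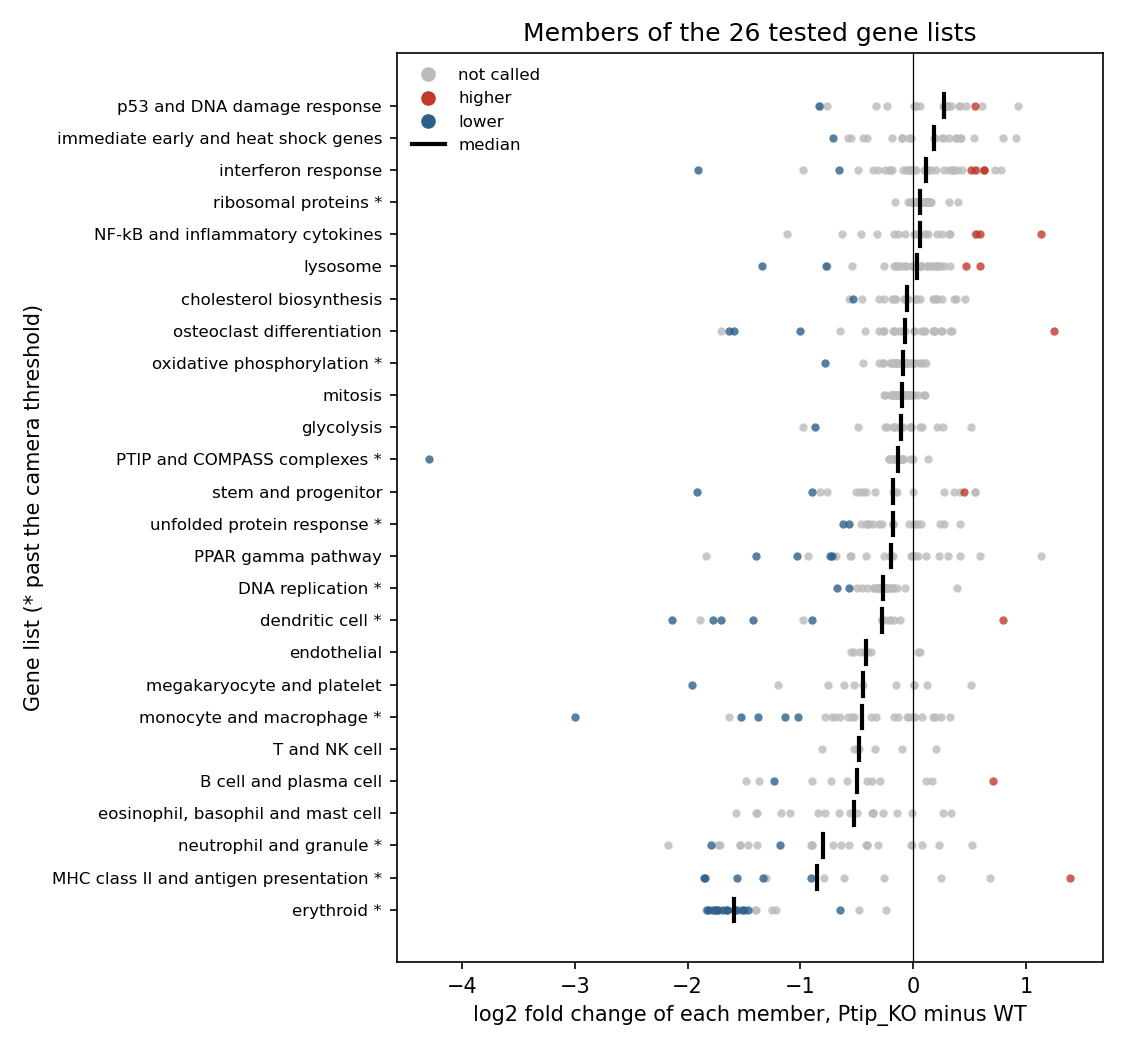
Each point is the log2 fold change of one tested member of a gene list, Ptip_KO minus WT, coloured red or blue where the gene passed the test, and black bars are list medians. The erythroid list has the lowest median, −1.59, and an asterisk marks the 10 of 26 lists past the camera threshold.

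Genes of DNA replication were slightly lower. Of 31 tested members, 2 fell and none rose, 30 had a negative log2 fold change, and the median was −0.27. Adjusted over the list alone, 1 rose and 17 fell. Cdc6 fell from 118 ± 2.21 to 74.2 ± 10.4 CPM (SD, n = 2) and the cyclin Ccne2 from 91.8 ± 4.56 to 61.6 ± 4.65 CPM. By edgeR, the adjusted p was 0.0537 for Cdc6, past the threshold no more, and 0.0395 for Ccne2. Both lost the call without Ptip_KO replicate 1, at limma adjusted p of 0.122 and 0.156, and Ccne2 also without Ptip_KO replicate 2 (0.0641). In the list, 0 members fell without Ptip_KO replicate 1 by limma, 1 without Ptip_KO replicate 2, 6 without WT replicate 2 and 15 by DESeq2, with 1 higher by DESeq2, edgeR and limma-voom and when rescaled to a common sum or by median-of-ratios factors. The list had a camera adjusted p of 2.3e-08, and adjusted p = 0.689 with an estimated correlation. In the mitosis list, 0 of 30 members passed by limma, edgeR or DESeq2, at an unadjusted limma p under 0.05, or adjusted over the list alone. Its camera adjusted p was 0.0656, and 0.000422 without Ptip_KO replicate 1, 0.0281 without WT replicate 2 and 0.0466 with no filter. Its median of −0.10 was −0.21 without Ptip_KO replicate 1, −0.03 without WT replicate 1 and −0.17 without WT replicate 2, and its direction turned to higher without Ptip_KO replicate 2 (median 0.01, camera adjusted p = 0.562).

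Changes in 3 further lists past the threshold were small and depended on single libraries. In the unfolded protein response list, 2 of 20 members fell (adjusted over the list alone, 6), the chaperone genes Pdia6 and Sdf2l1, with a median of −0.18, a camera adjusted p of 0.00676, 0.127 without Ptip_KO replicate 1, and adjusted p = 0.689 with an estimated correlation. By limma, 0 fell without Ptip_KO replicate 1 or 2 (median −0.31 without replicate 2), 4 without WT replicate 1 or 2, 1 when rescaled to a common sum, and 9 by DESeq2. In the oxidative phosphorylation list, 1 of 39 members, the cytochrome c gene Cycs, fell (adjusted over the list alone, 1), with a median of −0.09, a camera adjusted p of 0.0181, 0.372 without Ptip_KO replicate 2, 0.568 without WT replicate 1, 0.0685 by edgeR, and adjusted p = 0.809 with an estimated correlation. Its median was −0.15 without Ptip_KO replicate 1, −0.04 without Ptip_KO replicate 2, −0.01 without WT replicate 1 and −0.19 without WT replicate 2, and 3 members fell without WT replicate 2 and by DESeq2. In the ribosomal protein list, 0 of 44 members passed by limma, also adjusted over the list alone (2 at an unadjusted p under 0.05, 0 by edgeR, 2 by DESeq2), with a median of 0.06, a camera adjusted p of 0.0423, 0.0816 to 0.128 without each library in turn, 0.0685 by edgeR, and adjusted p = 0.774 with an estimated correlation.

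The remaining lists did not pass. For interferon response genes, which the Mx-1Cre driver shares its trigger with, 4 of 40 members rose and 2 fell (adjusted over the list alone, 4 and 3), at a camera adjusted p of 0.129, and 0.00152 without Ptip_KO replicate 1 and 0.0234 without WT replicate 1. The counts higher and lower were 2 and 0 without Ptip_KO replicate 1, 0 and 2 without Ptip_KO replicate 2, 9 and 3 without WT replicate 1, 7 and 4 without WT replicate 2, and 1 and 1 when rescaled to a common sum. Oas1a and Ifit2 rose by 0.63 and by 0.55 on the log2 scale, while Rsad2 fell by 1.91. In the p53 list, 1 of 24 members rose and 1 fell (adjusted over the list alone, 4 and 1), at a camera adjusted p of 0.0579, and 0.0183 without Ptip_KO replicate 1 and 0.0392 with no filter. Of its members, 0 rose by limma without Ptip_KO replicate 2, 2 rose and 2 fell without WT replicate 1, 4 rose without WT replicate 2 and by DESeq2, and 2 rose with no filter and when rescaled to a common sum. The NF-kB list had 3 of 21 members higher, the adhesion molecule Icam1, Nfkbie and Cd40, and none lower (adjusted over the list alone, 3 and 0; camera adjusted p = 0.225), but 0 were higher and 1 lower by limma without Ptip_KO replicate 1, 1 and 0 without Ptip_KO replicate 2, 6 and 1 without WT replicate 1, 3 and 2 without WT replicate 2, and 5 and 1 by DESeq2. Their median was 0.06, and −0.02 without Ptip_KO replicate 2 or WT replicate 2 and 0.25 and 0.29 without the other 2 libraries. Lysosomal genes had 2 of 35 higher and 2 lower (adjusted over the list alone, 2 and 3; camera adjusted p = 0.877), and 0 higher and 1 lower by limma without either Ptip_KO library, 5 and 4 without WT replicate 1, and 5 lower by DESeq2. Their median of 0.03 was −0.02 without Ptip_KO replicate 1, 0.10 without Ptip_KO replicate 2, 0.19 without WT replicate 1 and −0.12 without WT replicate 2. Glycolysis had 1 of 19 lower, Slc16a3 (adjusted over the list alone, 0 and 1; camera adjusted p = 0.132), with 0 lower by limma without Ptip_KO replicate 2, 2 without WT replicate 1, 3 without WT replicate 2 and 4 by DESeq2. Cholesterol biosynthesis had 1 of 24 lower, Sqle (adjusted over the list alone, 1 and 1; camera adjusted p = 0.919), and 1 higher and 2 lower by DESeq2. Sqle missed the threshold by edgeR (adjusted p = 0.0598), limma-voom, either rescaling, a pseudocount of 5, and limma without either Ptip_KO library. The direction of the list turned to higher without Ptip_KO replicate 2 or WT replicate 1 (medians 0.06 and 0.02). Immediate early and heat shock genes had 1 of 22 lower, Hspa8 (adjusted over the list alone, 0 and 0; camera adjusted p = 0.411), but passed as higher without Ptip_KO replicate 1 (5.77e-07, 5 members higher) and WT replicate 1 (0.0348, 3 higher) and as lower without Ptip_KO replicate 2 (0.009, 3 lower).

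Among lists of other marrow cells, stem and progenitor genes had 1 of 19 higher and 2 lower (adjusted over the list alone, 1 and 4; camera adjusted p = 0.209). Kit, the receptor of stem cell factor, fell from 61.3 ± 16.7 to 15.3 ± 1.18 CPM and Flt3 from 72.7 ± 7.22 to 38.7 ± 5.86 CPM (SD, n = 2). The B cell and plasma cell list had 1 of 12 higher, Cd79b, and 1 lower, Cd22 (adjusted over the list alone, 1 and 1; camera adjusted p = 0.0649), and the megakaryocyte list 1 of 11 lower, Pdzk1ip1 (adjusted over the list alone, 0 and 2; camera adjusted p = 0.186). Neither B cell gene passed by edgeR, limma-voom or either rescaling. Of 87 tested immunoglobulin genes, 10 were called lower and 1 higher by limma, against 477 and 300 of all 12357 tested genes. A negative log2 fold change was seen for 70 of the 87, with a median of −0.76. No member passed by limma or edgeR among 7 T and NK cell genes (camera adjusted p = 0.106), 18 genes of eosinophils, basophils and mast cells (0.0612) and 8 endothelial genes (0.0656), and adjusted over the list alone there were none either, but 2, 8 and 3 fell without WT replicate 1, and 1 gene of the eosinophil list rose without WT replicate 1 or 2. At an unadjusted limma p under 0.05 there were 1, 2 and 2 such genes, and DESeq2 called 1, 2 and 1. Of 24 stromal and osteoblast genes, 4 were above the filter, too few to test as a list, and none passed by limma, edgeR or DESeq2, at an unadjusted limma p under 0.05, or adjusted over the list alone. Without Ptip_KO replicate 2, and likewise without WT replicate 1, the stem, B cell, T and NK cell, megakaryocyte, eosinophil and endothelial lists passed the camera threshold, with adjusted p between 1.06e-06 and 0.0464, and the B cell list also without Ptip_KO replicate 1 (0.049). With no filter, the B cell (0.00434), T and NK cell (0.000117), megakaryocyte (0.0126) and eosinophil (0.0126) lists passed, and when rescaled to a common sum the B cell (0.039) and eosinophil (0.0393) lists. Without WT replicate 1, 7 stem and progenitor, 8 B cell and 5 megakaryocyte members fell, and without WT replicate 2, 6 stem and progenitor members rose. Of the genes of markers that the sort should exclude, Cd3e, Cd3d and Cd3g stayed at or under 0.418 CPM in each library, Itgam, which encodes a chain of Mac-1, was at 37.1 ± 2.90 CPM in Ptip_KO and 40.8 ± 1.75 CPM in WT (SD, n = 2), and Ptprc was at 479 ± 36.2 and 556 ± 74.0 CPM. Ptprc encodes B220 and also the CD45 forms of other blood cells, which counts per gene do not separate.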

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

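The runs with the authors' effective library sizes, with limma-voom, without near-identical copies and of the PTIP list without Paxip1 were chosen after the data were seen. The 777 calls (300 higher, 477 lower) numbered 585 to 902 under 9 settings of pseudocount, filter, scaling, variance prior or edgeR other than those named below, 755 with the authors' library sizes and 577 with limma-voom. DESeq2 called 1906 genes (780 higher, 1126 lower), and the cause was not tested. Leaving out 1 library gave 452 to 1620 calls, 113 to 700 higher and 339 to 920 lower, and 364 to 775 of the 777 past the threshold, with 3 libraries in each fit, the lone sample being assumed to vary like the other group. Without Ptip_KO replicate 1 or 2, 75% and 74.2% of calls were lower, against 61.4% with all libraries. The replicate block gave 1721 genes (691 higher, 1030 lower) and 14 lists, with mitosis, T and NK cell, eosinophil and endothelial genes added to the 10. The labels do not say that a shared number pairs the libraries, and across genes the deviations of the libraries numbered 1 correlated with 0.332. Of 26 lists, 10 passed, against 17 of 27 without a filter, where more members are tested, 11 to 16 without 1 library, 9 with edgeR, 10 without near-identical copies, 9 with Paxip1 left out of its list, 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 0 with the directional test of fry (6 at an unadjusted p under 0.05), whose smallest adjusted p was 0.161, while 14 passed by its test for members changed in either direction. With an estimated correlation, a simulated shifted set also missed the threshold, but its genes were drawn independently. The real erythroid list had an estimated correlation of 0.866, so the simulation does not explain the loss of its call. The unfolded protein response list lost its call as well, at an estimated correlation of −0.0205 (camera adjusted p = 0.689). Correlated members therefore do not account for the loss of every list call. Scaling to a common sum and by median-of-ratios factors moved the median of all genes by 0.049 and 0.0015 on the log2 scale. For 134 named genes, 2053 of 2264 alternative values kept their side of the threshold, 100 lost the call, 111 gained it and 0 called values reversed. The sign changed in 12 uncalled values. At this depth and n, changes of 1.5-fold are mostly missed.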

Other observations

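The tests on erythroid genes, on the pair of Gm15772 and Rpl26 and on sex, and the count over other splits, were chosen after the result was seen, and the others before. Of 185 gene families named by symbol, tested in both directions, none was enriched past the threshold by Fisher's exact test (12 tests at an unadjusted p under 0.05), and the smallest adjusted p was 0.0952, for 5 of 16 C-type lectin (Clec) genes that fell.

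Erythroid genes were lower together in Ptip_KO. They fell further than the other non-target lists: the erythroid median minus that of 79 members of those lists (−0.49) was −1.09. The permutation p was 1e-05, the smallest that 100000 permutations give, although genes are not independent. The difference ran from −0.938 to −1.17 with each library left out in turn. The log2(CPM + 1) scale understates changes of low genes. On recovered reads by edgeR, however, the erythroid median was −1.73, and those of the other non-target lists lay between −0.81 and −0.53. These values argue against a higher purity of the main cell type that lowers every other type alike, and the bound written against it after the result was seen was met. Of the 79 members, 64 also had a negative log2 fold change, so a higher purity as part of the change stays open. A smaller share of erythroid cells or their RNA in the Ptip_KO libraries stays open, since the middle portion of members, from the first to the third quartile, spanned 0.338 on the log2 scale (0.556 without Ptip_KO replicate 1) and globin and haem genes were among them, with Hbb-bt (−0.48) and Tfrc (−0.65) apart from the rest. The CD115 gate should exclude such cells, although Hbb-bs averaged 1910 CPM in WT and 23 of the list's 24 genes passed the filter, and 0 of the 23 are held by another list. A change in erythroid gene expression within the sorted cells was not tested and stays open too.

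Near-identical copies may account for part of the largest increases. Of 70 called genes with an absolute log2 fold change of at least 2, 15 had such a copy (21.4%), against 12.1% of other tested genes, an odds ratio of 1.98 (95% interval 1.03 to 3.56, Fisher's exact p = 0.0259). The excess lay in the increases, with 8 of 20 higher genes (an odds ratio of 4.83, 95% interval 1.71 to 12.9) against 7 of 50 lower genes (1.18, 0.447 to 2.65), which differed by Fisher's exact test (p = 0.0249), a split made after the result was seen. For Gm15772 and Rpl26, the summed CPM was 579 ± 1.58 in Ptip_KO and 564 ± 2.37 in WT (SD, n = 2), a log2 difference of 0.0388, while the members changed by 6.05 and −1.55, which is consistent with reads moving from one copy to the other. What moves them, such as a sequence difference between the mice, was not tested, and the excess over other genes leaves most of the 70 genes without a copy. Gm15772 and Rpl26 were the only pair in which a gene called higher had a near-identical copy called lower. Moved reads were therefore not shown for the other increases that have a copy.

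Large changes of neighbours such as Nlrp1a and Nlrp1b or the Trim genes raise the hypothesis that haplotypes of the mixed B6;129 background differ between the groups. Of 103 genes at least 2-fold higher, 40 had another called gene of a different family within 1 Mb that was at least 2-fold higher or lower. The median in 10000 relabellings was 45 (5th to 95th percentile 36 to 54, permutation p = 0.84). The count lay under the median, which had been set beforehand as the bound against this explanation, but inside the spread of the relabellings, a requirement added after the count was seen, and it leaves out neighbours of 1 family, so haplotypes and the knockout cannot be told apart for these genes. Sequence flanking the floxed Paxip1 allele showed no excess of calls, since 8 of 138 genes within 10 Mb of Paxip1 were called, an odds ratio of 0.917 (95% interval 0.386 to 1.87). The upper limit met the bound set beforehand against this explanation, but the interval still includes an excess. Flanking sequence beyond 10 Mb was not tested, and Gm15772 and Gm15459 lie on chromosome 5 outside that window.

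Sex of the mice is argued against as the source of the calls as a set. Among 1495 genes called without the male WT replicate 1, that library lay at a median share of 0.775 of the way from the mean of the male Ptip_KO libraries to the female WT replicate 2 (interquartile range 0.503 to 1.08), where sex as the source puts it near 0, as for Ddx3y (0.0489). This rests on 1 male WT library, and sex stays open for single genes. Of these genes, 75.3% lay nearer the female WT library than the Ptip_KO mean. The bound on the first quartile, written after the result was seen, was only just met. The count planned beforehand, 777 of 777 calls that kept their direction and an unadjusted p under 0.05 without the female library, was also reached without each male library and decides nothing. The real split called 777 genes by limma and the highest of the other splits called 0 (467 and 47 genes at an unadjusted p under 0.05), and with 3 splits of 4 libraries, of which 1 called as many, no share under 0.05 can be reached.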
